A study of Mus musculus with 8 samples.

How the data were processed

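RNA from mouse spleen NK cells was measured on 8 one-colour (Cy3) Agilent arrays. Per the series' design text and the labels, NK cells were enriched magnetically and sorted by a ChAT-eGFP reporter, which marks cells that express choline acetyltransferase, and cells of 2 to 4 mice were pooled for each sample. Per the labels' protocols, 100 ng of total RNA was amplified by in vitro transcription before labelling. The labels give 4 pools with the reporter (ChAT_positive) and 4 without it (ChAT_negative). The labels do not say whether the pools of a group shared mice, so the p-values measure the spread between these samples, which may be technical in part.

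The deposited scanner files hold spot intensities on a linear scale and flags per spot. Per the file headers, Agilent Feature Extraction 11.5.1.1 made them, and the processed intensity is already background-subtracted within each array and not scaled between arrays. Which rule chose the probes of the deposited value table is not given in the sources used here. The deposited value table holds log2 values for 31942 probes. Set against the scanner values of the same array, each of its columns followed log2 of the processed intensity less one constant close to that array's 75th percentile, with the largest gap at -0.0065 for ChAT_negative replicate 4, so its values are not centred per gene. The medians of its columns lie between -0.72 and -0.63. No column lacked a sample.

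Each array holds 62976 spots, of which 59305 are not controls and form 55681 probes. Control spots and 1344 outlier-flagged spot values were left out, and 51 probe values whose spots were all flagged were kept. The spots of a probe were averaged. A total of 26762 probes were named with 1 gene symbol through an unversioned RefSeq accession in a table of the GRCm38.p6 assembly, and 28919 were not named here. No gene positions are given, because the array was annotated on an earlier mouse assembly than that table, per the file headers. The main values are log2 of the processed intensity minus each array's 75th percentile over non-control probes. Probes well above background on at least 4 of the 8 arrays were kept (32087 probes). The brightest probe of each gene over all arrays stood for the gene, which left 13608 genes. Signal over background sets the depth of an array: between 50.2% and 63.2% of non-control spots were well above background, and 0 spots were saturated. The number of arrays limits the precision.

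ChAT_positive was compared with ChAT_negative with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over genes, adjusted p under 0.05), with no block. Fold changes are ChAT_positive minus ChAT_negative. A gene not well above background on any array of a group, by any probe, is given as "at least N-fold". That bound sets the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest signal among probes well above background and the gene's own signal. For Foxo6 the bound is that of its probe alone. These bounds compare means and hold no sampling error, so a 95% interval of the fold change can reach below them. A total of 24 pathway lists and 12 cell type marker lists were tested with camera (preset correlation 0.01, lists of 5 or more tested genes, Benjamini-Hochberg over lists), and again with an estimated correlation and with fry. Of 665 list members, 645 matched a symbol on the array.

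The lists, the test, the alternatives and the rule for named genes were fixed before the data were examined. The rule names Chat, then the 12 largest differences in each direction among called genes whose groups do not overlap and that are well above background on all 4 arrays of the higher group, leaving out provisional names and immunoglobulin or T cell receptor segments. It then names up to 4 members per described list by adjusted p, or the 2 brightest where none passed, and 12 anchor genes. A few genes that the rule takes are not reported here. A few further lists (type 2 lymphoid, type 17 lymphoid and kallikrein 1 family transcripts) were chosen after the values were seen. Alternatives changed the scaling, background correction, dim-probe filter, probe choice, variance model, array weights, block, threshold and set test, used the deposited table, and left out arrays. The normexp alternative used the median spot signal, since a mean signal was not among the columns used here. All arrays of a group lay on 1 slide and in 1 scan of their own, so neither could be a block.

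The procedure was tested on simulated data for this comparison, with 200 of 13608 genes changed at the measured spread. It recovered 66% of the genes changed 2-fold and 92% of those changed 4-fold, and 5.95% of its calls were false. The simulated spread was independent between genes and held no slide difference, so the share of false calls in the real comparison may differ.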

Results

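Gene expression was measured in mouse spleen NK cells sorted by a ChAT-eGFP reporter, in 4 ChAT_positive and 4 ChAT_negative pools, with 50.2% to 63.2% of spots per array well above background. The comparison asks which transcripts differ between NK cells with and without reporter expression of choline acetyltransferase, the enzyme that makes acetylcholine. Of 13608 genes tested with limma, 382 were higher and 428 lower in ChAT_positive cells, and 95 were higher and 227 lower by at least 2-fold. The groups did not overlap for 15.5% of genes, where chance gives 2.86%. All 4 arrays of a group lay on 1 slide of their own, so slide and reporter group cannot be told apart for any difference below. The counts depended on single arrays: 155 higher and 196 lower without ChAT_positive replicate 1, 100 and 123 without ChAT_positive replicate 3, 197 and 284 without ChAT_positive replicate 4, 181 and 251 without ChAT_negative replicate 2, 149 and 225 without ChAT_negative replicate 3, and 94 and 116 without ChAT_negative replicate 4. Of genes at least 2-fold different, 58 were higher without ChAT_positive replicate 3 and 59 without ChAT_negative replicate 4. At least 2-fold lower were 145 without ChAT_positive replicate 1, 94 without ChAT_positive replicate 3, 142 without ChAT_negative replicate 3 and 91 without ChAT_negative replicate 4. Under quantile normalization 512 genes were higher and 396 lower, 114 and 172 by at least 2-fold. With probes required well above background on all 8 arrays 474 were higher and 455 lower, 81 and 175 by at least 2-fold. The direction with more calls thus depended on these choices, except among calls of at least 2-fold, where more were lower each time. Without both arrays numbered 3, whose signal was the lowest of their group for 9 of 10 spike-in probes, 21 genes were higher and 35 lower (an alternative chosen after seeing the data).

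**Figure D1:**
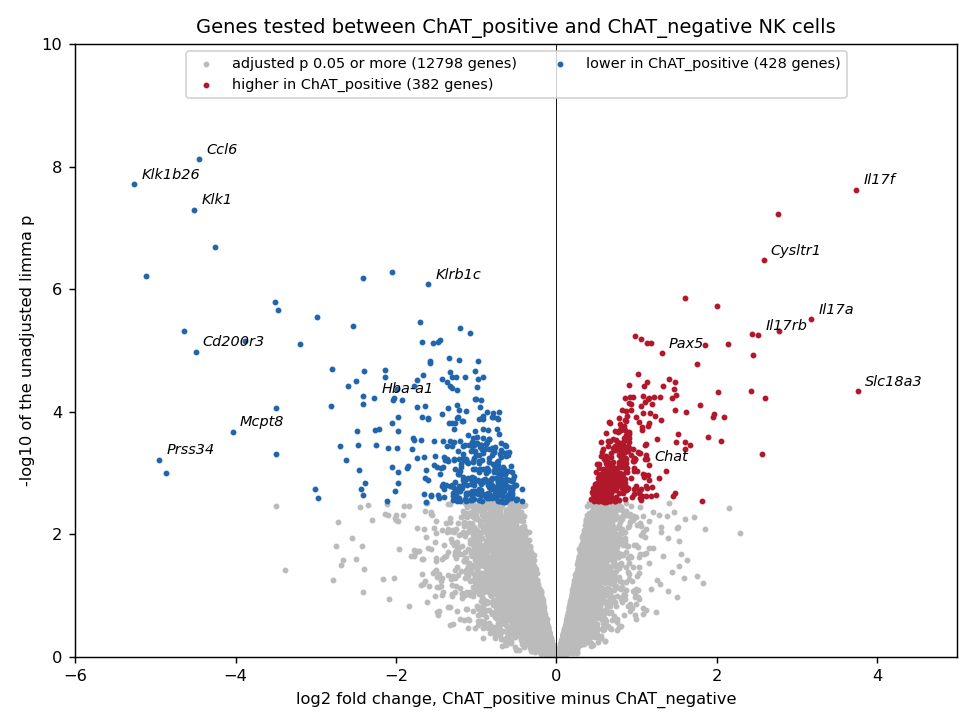
Log2 fold change (ChAT_positive minus ChAT_negative) against -log10 of the unadjusted limma p, 1 point per gene tested. Red points are the 382 genes higher and blue points the 428 genes lower in ChAT_positive at an adjusted p under 0.05.

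Chat was higher in the ChAT_positive pools, in the direction the sort implies. Its 1 probe gave a log2 signal of 3.75 ± 0.25 (SD, n = 4) against 2.65 ± 0.34 (SD, n = 4), a log2 fold change of 1.10 (SE 0.20, limma adjusted p = 0.0201) or 2.15-fold (95% interval 1.57 to 2.94), and was well above background on all 8 arrays. The two-sided exact permutation test gave p = 0.0286, the smallest that 4 against 4 arrays allow. The ChAT_negative pools also held Chat signal, at an unscaled processed intensity of 11969 to 18181 against 24343 to 30849 in ChAT_positive pools. The groups therefore differed in the level of this probe's signal and not in its presence, which limits how the differences below can be read. With 1 Chat probe, whether all of that signal came from Chat transcript could not be checked. Slc18a3, the vesicular acetylcholine transporter, rose by a log2 fold change of 3.76 (SE 0.51, adjusted p = 0.00796), and was well above background on 4 of 4 ChAT_positive and 1 of 4 ChAT_negative arrays, so the size of that rise rests on signal near background. These were the 2 genes called among 9 tested genes of acetylcholine synthesis, transport and breakdown, with 3 higher and 1 lower adjusted over the list alone. None of the 5 tested acetylcholine receptor genes was called by limma, with 1 lower at an unadjusted p under 0.05, and Chrnb1 had a log2 fold change of -0.075. Of the genes of synthesis, transport and breakdown, 1 was called with no filter on dim probes or one at all 8 arrays. The Chat call was lost without ChAT_positive replicate 3 (adjusted p = 0.0625) and without ChAT_negative replicate 4 (0.0648).

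Interleukin 17 genes were among the 12 largest rises that the rule takes. Il17f, a cytokine of type 17 responses, had a log2 signal of 2.15 ± 0.24 (SD, n = 4) in ChAT_positive and -1.59 ± 0.38 (SD, n = 4) in ChAT_negative pools, a log2 fold change of 3.74 (SE 0.21, limma adjusted p = 1.08e-04). Il17a, another cytokine of these responses, rose by 3.18 (SE 0.31). Il17rb, the receptor for IL-25, rose by 2.52 (SE 0.26), the epidermal growth factor family ligand Areg by 2.60 (SE 0.37), the leukotriene receptor Cysltr1 by 2.58 (SE 0.20) and the chemokine receptor Ccr4 by 2.77 (SE 0.29). Trpm6, Hlf, Cxcl3 and Gja1 were also among these 12, at log2 fold changes of 2.44, 2.42, 2.13 and 2.09. Of the ChAT_negative arrays, 1 of 4 was well above background for Ccr4, 1 of 4 for Trpm6 and 3 of 4 for Gja1, so the sizes of the Ccr4 and Trpm6 rises rest on signal near background. All 12 kept their call whichever single array was left out. Of 11 tested NKT and ILC2/ILC3 markers, 4 rose, among them Il17a, Il17rb and Il1r1, and 0 fell, and 7 were higher and 1 lower adjusted over the list alone. Without ChAT_positive replicate 2, 1 of these markers was called lower, Ncr1 (limma adjusted p = 0.0224), which also stands in the NK identity list. The list's median was 0.95 (camera adjusted p = 1.34e-04), with adjusted p = 0.463 with an estimated correlation. Of 21 tested cytokines 2 rose, Il17a and Il13, the latter by 1.50 (SE 0.21), and 4 were higher and 2 lower adjusted over the list alone. The cytokines called higher numbered 4 without ChAT_negative replicate 1 or with array weights, and those called lower numbered 2 without ChAT_positive replicate 2, with array weights or with a trended and robust variance, and 0 with no filter on dim probes. Osm, which encodes oncostatin M, was the 1 that fell, by 1.19, and its call held without ChAT_positive replicate 2 or ChAT_negative replicate 1, and was lost without any other array (adjusted p up to 0.0866, without ChAT_positive replicate 3).

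**Figure D2:**
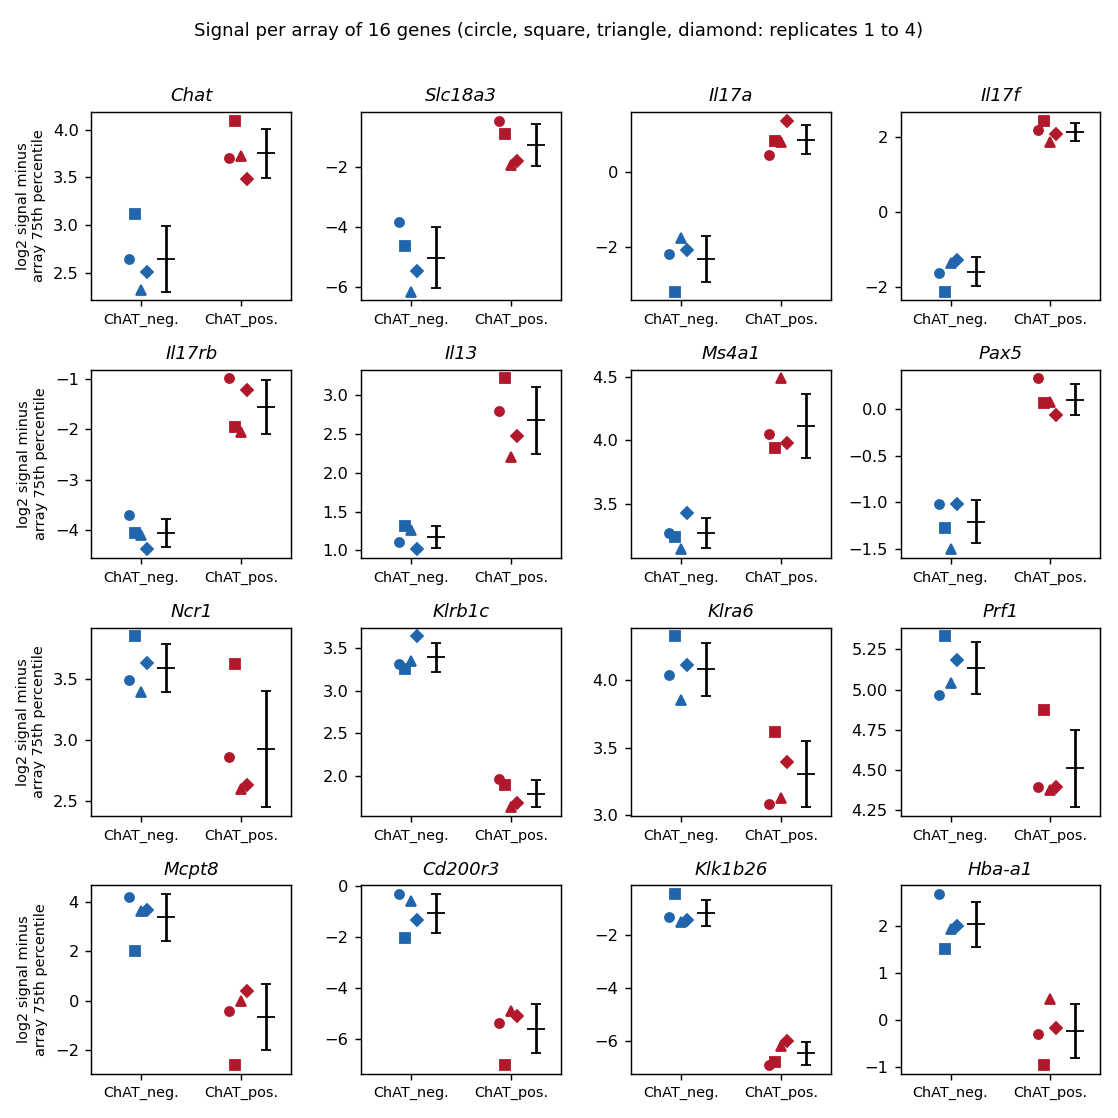
Log2 signal minus the array's 75th percentile for 16 genes, 1 point per array (blue ChAT_negative, red ChAT_positive), with the mean and SD of each group of 4 as the bar beside it; axes differ between genes. The groups do not overlap for Chat, Il17a, Il17f and Klrb1c, and they overlap for Ncr1.

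B cell transcripts were also higher in the ChAT_positive pools. Of 19 tested B cell markers, 7 rose and 0 fell, with 10 higher adjusted over the list alone and a median log2 fold change of 0.59. Pax5, the transcription factor of B cell identity, rose by 1.31 (SE 0.15, limma adjusted p = 0.0039), Bank1 by 1.12, Ebf1 by 1.03 and Ms4a1, which encodes CD20, by 0.84, from 3.27 ± 0.12 to 4.11 ± 0.25 (SD, n = 4 each). Pax5, Bank1, Ebf1 and Ms4a1 kept their calls whichever single array was left out. The markers called numbered 4 without ChAT_positive replicate 1 or 3 or ChAT_negative replicate 3 or 4, and 3 with no filter on dim probes. The camera call of the list (adjusted p = 5.09e-07) had adjusted p = 0.463 with an estimated correlation. MHC class II presentation genes had a median of 0.51, with 2 of 13 called higher and 8 higher adjusted over the list alone (Cd86 and H2-Oa; camera adjusted p = 1.34e-04, adjusted p = 0.503 with an estimated correlation). Called higher were 8 under quantile normalization, 6 with a trended and robust variance, 4 with a gene's probes averaged, 1 under median scaling and 0 with no filter on dim probes or one at 1 of 8 arrays. The H2-Oa call was lost whichever array was left out, and that of Cd86 without any except ChAT_negative replicate 1 or 2 (adjusted p up to 0.124 and 0.0991, both without ChAT_positive replicate 3). Type I interferon response genes had a median of 0.38, with 1 of 28 called and 10 higher adjusted over the list alone (camera adjusted p = 1.89e-06, adjusted p = 0.536 with an estimated correlation). Of that list, 4 genes were called without ChAT_negative replicate 1, and 0 without ChAT_positive replicate 1, 3 or 4 or ChAT_negative replicate 2, 3 or 4. With all arrays the number ranged over the alternatives from 0, with no filter on dim probes or one at 1 of 8 arrays, to 7 with array weights. No T cell marker was called among 19 by limma (1 higher and 3 lower at an unadjusted p under 0.05), and that list's median was -0.068; 2 markers were called lower without ChAT_positive replicate 2, 2 without ChAT_negative replicate 1, and 1 under normexp, array weights, a trended and robust variance or a filter at all 8 arrays. Cd3e, a subunit of the T cell receptor complex, had a log2 signal of 1.51 ± 0.50 against 1.04 ± 0.43 (SD, n = 4 each; limma adjusted p = 0.342).

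NK identity and Ly49 receptor genes that passed the test were lower in the ChAT_positive pools, 4 of 24 and 4 of 10. Klrb1c, which encodes NK1.1, had a log2 signal of 1.79 ± 0.16 (SD, n = 4) in ChAT_positive and 3.39 ± 0.17 (SD, n = 4) in ChAT_negative pools and fell by 1.60 (SE 0.13, limma adjusted p = 0.00103). Of 24 tested NK identity genes, 4 fell (Klrb1c, Sh2d1b1, Klrk1 and Klri2) and 0 rose, with 14 lower and 1 higher adjusted over the list alone and a median log2 fold change of -0.51. Among 10 tested Ly49 receptor genes, a family of close paralogs whose probes may share signal, 4 fell and the median was -0.69. The number of NK identity genes lower was 10 without ChAT_positive replicate 2, and the number of Ly49 genes lower was 8 without that array, 1 without ChAT_positive replicate 1 or 3 or ChAT_negative replicate 4, and 2 without ChAT_positive replicate 4 or ChAT_negative replicate 2. With array weights or a trended and robust variance 8 of each list were lower, and with no filter on dim probes 1 Ly49 gene was. Both lists were called by camera (adjusted p = 6.28e-08 and 4.38e-07), each with adjusted p = 0.463 with an estimated correlation. Fry called both (adjusted p = 0.042 and 0.0208). The activating receptor Ncr1 had a log2 fold change of -0.66 (adjusted p = 0.122), Eomes one of -0.53 (0.133) and Tbx21 one of 0.018 (0.953), so none of these 3 was called. Ncr1 was called without ChAT_positive replicate 2 (adjusted p = 0.0224), and Tbx21 changed sign under normexp and without any of 5 single arrays.

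Cytotoxic genes were lower as a list. Of 21 tested, 3 fell (Fasl, Gzmd and Prf1) and 0 rose, with 11 lower and 2 higher adjusted over the list alone, the median was -0.47 and the camera adjusted p was 6.74e-05 (adjusted p = 0.463 with an estimated correlation). Prf1, the pore-forming protein of cytotoxic granules, fell by 0.62 with an adjusted p of 0.0481 by limma. That call was lost without any 1 array except ChAT_positive replicate 2 (adjusted p up to 0.132, without ChAT_positive replicate 3). Of the list, 0 genes were called without ChAT_positive replicate 1 or 3 or ChAT_negative replicate 2, 3 or 4, 2 without ChAT_positive replicate 4 and 6 without ChAT_negative replicate 1, and with all arrays 0 were called with no filter on dim probes and 9 with array weights. Gzmd was well above background on 1 of 4 ChAT_positive arrays. Gzmb had a log2 fold change of -0.34 (adjusted p = 0.138), Ifng one of -0.20 (0.509) and Tnf one of 0.33 (0.31). Late NK maturation genes (2 of 14 called lower, Prdm1 and Cma1) and inhibitory receptors (3 of 18, Tigit, Entpd1 and Cd96) had medians of -0.44 and -0.32, with adjusted p = 0.463 and 0.501 with an estimated correlation. With no filter on dim probes 0 genes of either list were called, and with array weights, normexp or a trended and robust variance 5 late maturation genes. Prdm1 kept its call whichever array was left out. With 1 array left out, the calls of Cma1, Entpd1 and Cd96 held only where it was ChAT_positive replicate 2 or ChAT_negative replicate 1, and that of Tigit was lost without ChAT_positive replicate 3 or 4 or ChAT_negative replicate 1, 3 or 4. Highest were adjusted p = 0.136, 0.128, 0.128 and 0.0876, all without ChAT_positive replicate 3.

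Transcripts of basophils and mast cells fell furthest among the fixed lists. All 8 tested markers had lower means in ChAT_positive pools, 5 fell, 8 were lower adjusted over the list alone, and the median was -3.24, or -3.19 with genes at their bounds. Mcpt8, a basophil granule protease, had a log2 signal of -0.66 ± 1.34 (SD, n = 4) against 3.37 ± 0.94 (SD, n = 4) and fell by 4.04 (SE 0.68, limma adjusted p = 0.016). Cd200r3 was at least 15.2-fold lower, since it was well above background on 0 of 4 ChAT_positive arrays. The 95% interval of its measured fold change reached below that bound, to 10.1-fold. Prss34 fell by 4.95 and Fcer1a, a subunit of the high-affinity IgE receptor, by 4.86, each well above background on 3 of 4 ChAT_positive arrays. Of the 8 markers, 2 were called without ChAT_negative replicate 4, where Mcpt8 (adjusted p = 0.0547), Prss34 (0.0707) and Fcer1a (0.0874) were not, and 3 without ChAT_positive replicate 3 or ChAT_negative replicate 3, where Prss34 and Fcer1a were not; the Fcer1a call was also lost without ChAT_positive replicate 1 or ChAT_negative replicate 1. Camera called the list (adjusted p = 9.79e-08), with adjusted p = 0.463 with an estimated correlation. Erythroid (3 of 11 lower), platelet (2 of 12) and neutrophil markers (3 of 17) had medians of -0.88, -0.89 and -1.46, with adjusted p = 0.463, 0.463 and 0.538 with an estimated correlation. The haemoglobin gene Hba-a1 fell by 2.27 (SE 0.32) and the platelet receptor gene Clec1b by 2.22. The erythroid calls were Car2, Hba-a1 and its close paralog Hba-a2, whose probes may share signal. Lyz2, a myeloid lysozyme, had a log2 fold change of -1.09 (SE 0.89, adjusted p = 0.488). Of neutrophil markers, 0 were called without ChAT_negative replicate 3 or 4, 1 without ChAT_positive replicate 1 or 4 and 2 without ChAT_positive replicate 3 or ChAT_negative replicate 2 and, of platelet markers, 1 without ChAT_positive replicate 1 or 3 or ChAT_negative replicate 3 or 4 and 4 without ChAT_negative replicate 2. With no filter on dim probes 0 neutrophil markers and 1 platelet marker were called, and under normexp 8 basophil, 5 erythroid and 4 platelet markers. Hba-a1 and Clec1b kept their calls whichever array was left out.

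The other large falls included 5 genes of the kallikrein 1 family, near-identical paralogs whose probes cannot be assumed to tell them apart. Klk1b26 was at least 15.3-fold lower, Klk1b5 at least 20.3-fold, Klk1 at least 11.1-fold, Klk1b24 at least 4.88-fold and Klk1b16 at least 2.72-fold, each well above background on 0 of 4 ChAT_positive and 4 of 4 ChAT_negative arrays. For Klk1b5 the 95% interval of the measured fold change reached below the bound, to 18.1-fold. The chemokine gene Ccl6 fell by 4.46 (SE 0.22, limma adjusted p = 1.03e-04). The epithelial cadherin gene Cdh1 fell by 4.65 (SE 0.48), with 1 of 4 ChAT_positive arrays well above background, so the size of that fall rests on signal near background. The transcription factor gene Foxo6 was at least 12.5-fold lower by a probe well above background on 0 of 4 ChAT_positive and 4 of 4 ChAT_negative arrays, and its other probe was above background on 1 and 2 of them. For Foxo6 the 95% interval of the measured fold change reached below the bound, to 7.60-fold. Of the 12 largest falls that the rule names, 9 kept their call whichever single array was left out, all except Prss34, Fcer1a and Mcpt8; without ChAT_negative replicate 4 these had adjusted p = 0.0707, 0.0874 and 0.0547.

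**Figure D3:**
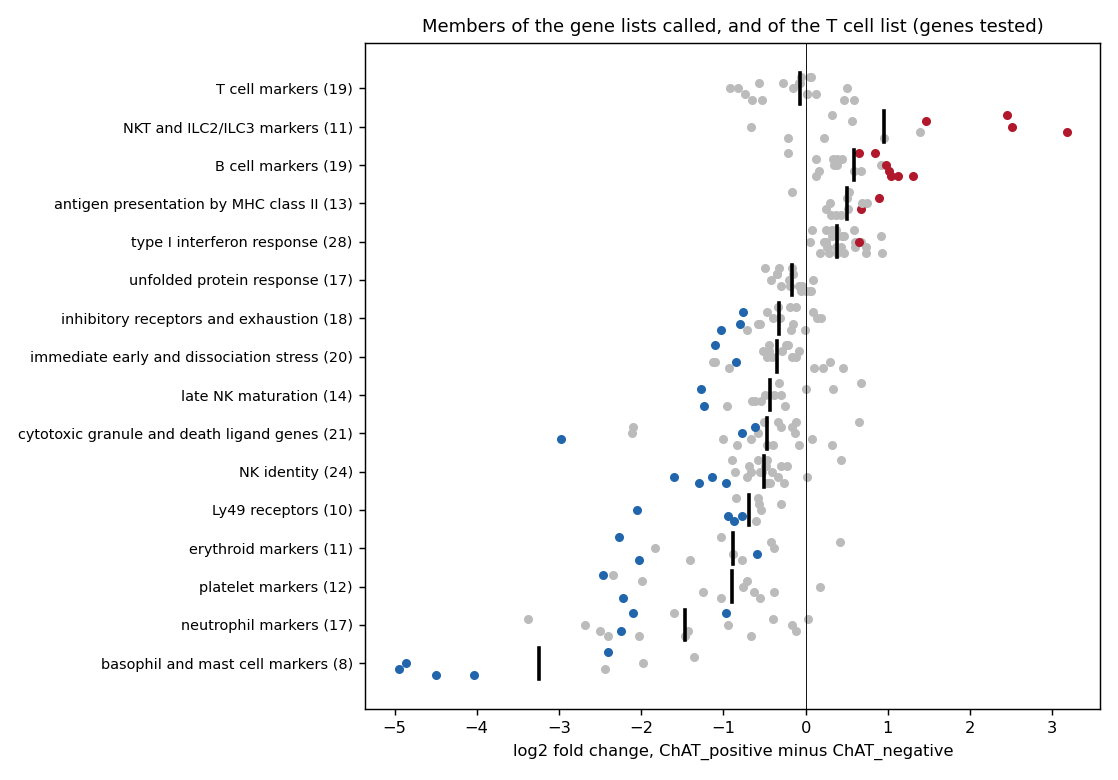
Log2 fold change of each tested member of the 15 gene lists called by camera and of the T cell list, with the number of tested genes in parentheses and the list median as a black bar. Red and blue points are genes called higher and lower in ChAT_positive, and grey points were not called; basophil and mast cell markers have a median of -3.24 and NKT and ILC2/ILC3 markers one of 0.95.

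In all, camera called 15 of 36 lists with the preset correlation, and 0 with the estimated correlation, where 2 had an unadjusted p under 0.05. Fry called 7 lists: NK identity, Ly49, late NK maturation and cytotoxic genes, and B cell, basophil and mast cell, and NKT and ILC2/ILC3 markers. Their fry adjusted p lay between 0.0196 and 0.042. The other 2 lists that camera called were immediate early genes and the unfolded protein response. Of immediate early genes 2 of 20 were lower, Btg2 and Fosl2 (median -0.35, adjusted p = 0.577 with an estimated correlation). Of the unfolded protein response 0 of 17 were called by limma, with 3 lower at an unadjusted p under 0.05. Its median was -0.16 (adjusted p = 0.698 with an estimated correlation). Of the immediate early genes 0 were called without ChAT_positive replicate 3, 1 without ChAT_negative replicate 4 and 4 under normexp, a trended and robust variance or a filter at all 8 arrays, and the call of the unfolded protein response list was lost without ChAT_positive replicate 1 (adjusted p = 0.0592), ChAT_positive replicate 4 (0.169) or ChAT_negative replicate 1 (0.177). Among lists not called, cell cycle genes had a median of 0.13, glycolysis genes one of -0.091, oxidative phosphorylation genes one of -0.039, cytosolic ribosomal proteins one of -0.079 and monocyte and macrophage markers one of -0.086. The median and mean differed in sign for chemokine and homing receptors (-0.17 and 0.019) and for stroma and endothelium markers (-0.072 and 0.094), and camera took chemokines (median 0.14) and the TGF-beta pathway (0.085) as lower, without calling either. Single genes of uncalled lists differed: Ccr9 fell by 2.50 and Itgax by 1.31, and Lum, an extracellular matrix proteoglycan, rose by 2.05. The Lum call was lost without ChAT_negative replicate 4 (adjusted p = 0.0514).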

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

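The tests of explanations in this part were all chosen after the results were seen. Of 280 groups of 4 arrays examined (103 genes and 36 list scores in each reporter group, and the share of spots above background), 16 held an array far from the other 3 by Dixon's criterion, and chance gives about 5%. Of these, 13 were arrays numbered 2. In ChAT_positive replicate 2 the log2 signal was -5.34 for Prss34, 3.38 for Eomes, 4.87 for Prf1, 1.72 for Cma1, -0.63 for Entpd1 and -1.78 for Lyz1, and the mean signal was 2.52 for NK identity, 2.76 for early NK maturation and 1.48 for immediate early genes. In ChAT_negative replicate 2 it was -0.0097 for Klk1b5, -1.32 for Fcer1a and -1.90 for Lyz2, and the mean was -0.82 for neutrophil markers. The others were Tbx21 in ChAT_negative replicate 4 (3.37), Klri2 in ChAT_negative replicate 1 (2.38) and the B cell list in ChAT_positive replicate 3 (2.59). Among probes with no gene name here, 410 were called between the groups.

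Of the 35 splits of the 8 arrays into 4 and 4, 1 (the real one) called as many as 810 genes and the highest other called 30. This argues against a chance split of these arrays, at 1 of 35, the fewest that the test can give. The real split is also the split by slide, so the test does not tell reporter from slide. For differences of at least 2-fold the real split called 322 and the highest other 27, again 1 split of 35. For the number of lists chance cannot be excluded: 3 of the 35 splits called at least as many as the real 15, and the highest other called 17.

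Of 11 NKT and ILC2/ILC3 markers 4 were called higher in ChAT_positive pools and 0 lower. The list's call was lost with an estimated correlation (adjusted p = 0.463) and kept with fry (adjusted p = 0.0196). A larger share of T cells may add such transcripts. The T cell list had a median of -0.068, but Cd3d, Cd3e and Cd3g were well above background on all 8 arrays, a baseline that could hide a small share, so this stays open. The slides cannot be told apart from the groups, since 0 slides hold both, and 3 of the 11 tested markers stand in another list too. A larger share of innate lymphoid or NKT cells, and a difference between NK cells with and without the reporter, stay open as untested.

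Of 8 basophil and mast cell markers 5 were called lower in ChAT_positive pools. The list's call was lost with an estimated correlation (adjusted p = 0.463) and kept with fry (adjusted p = 0.0208). Between-array scaling alone is argued against, since the list median was still -3.23 under quantile normalization. If these pools held fewer basophils or mast cells, the markers should vary together within groups. The 8 markers, 0 of which stand in another list, correlated at 0.61 within groups. That was above 100% of 10000 random lists matched on signal, and above 99.72% without both arrays numbered 2. The estimated correlations of the other fixed lists ran from -0.039 (stroma and endothelium markers) to 0.91 (cytosolic ribosomal proteins). Lists that mark no basophils thus also reached such values, so the test could not decide this hypothesis, which stays open. The mean log2 signal was -0.66 in ChAT_positive against 3.37 in ChAT_negative pools for Mcpt8 and -2.43 against 2.52 for Prss34, and whether the magnetic isolation or the sort removed such cells is not stated in the labels. The correlation shows a level that varied jointly between pools, not why the groups differ, and with 0 slides holding both groups slide stays open, as does an untested difference between the NK cells.

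Of Ncr1 and 16 Klr genes 7 were called lower in ChAT_positive pools, Ncr1 not among them. The calls of both the NK identity and the Ly49 list were lost with an estimated correlation (adjusted p = 0.463 for each). With fry both were kept (adjusted p = 0.042 and 0.0208). If fewer NK cells were the cause, Ncr1 and 16 Klr genes would fall by 1 factor, provided that only NK cells held these transcripts. With each array's mean over them removed, 6 of 17 genes had non-overlapping groups, as many in 1 of 35 splits. Relative to that mean, Klrb1c (-0.74) and Klra17 (-1.19) were lower in ChAT_positive pools. Klra1 (0.26), Klra4 (0.29), Klra7 (0.32) and Klra8 (0.30) were higher relative to it, so these had fallen by less than the mean. With the near-background Klra17 left out 3 of 16 genes had non-overlapping groups (as many in 2 of 35 splits), with the median removed in place of the mean 2 of 17 (4 splits), and with both changes 1 of 16 (11 splits). Dilution therefore cannot be told apart from a change in these genes, nor can slide, with 0 slides holding both groups.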

How the results depend on the processing

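The 2 alternatives without both arrays of one number were chosen after seeing the data. Of 810 called genes, 810 kept their direction under quantile normalization and 809 under normexp, and 691 and 660 were still called. Leaving out 1 array cannot turn the direction of the 799 whose groups do not overlap, but it changed the number past the threshold. With 1 array left out, genes higher ranged from 94 to 305, genes lower from 116 to 429, at least 2-fold higher from 58 to 116 and lower from 91 to 249, and the Chat log2 fold change from 0.99 to 1.26. Of 76 named genes called, 40 kept their call in all 8 such fits, 61 without both arrays numbered 2 and 21 without both arrays numbered 3. Without both arrays numbered 2, 193 genes were higher and 344 lower. Without both arrays numbered 3, 21 were higher and 35 lower, 19 and 35 by at least 2-fold, and Chat at 1.00 was not called (adjusted p = 0.118). Fewer arrays take part in this by construction, and the rest of the cause was not tested. With no filter on dim probes, where more genes are tested, 98 were higher and 126 lower, 103 lower by at least 2-fold, and Chat at 1.10 was not called (adjusted p = 0.053). Array weights gave 577 higher, and probes counted one by one gave 178 at least 2-fold higher; the cause was not tested. At an adjusted p under 0.01, 44 were higher and 60 lower (37 and 54 by at least 2-fold), and under 0.1, 866 and 837. Camera with an estimated correlation called 0 lists and fry called 7. Of the 15 lists called, 1 lost its call under each of median scaling, array weights, the deposited table and a filter at 1 of 8 arrays. So did 1 with the replicate block and 1 without both arrays numbered 3. Tbx21, never called, changed sign under normexp (-0.10), array weights (-0.079), without both arrays numbered 2 (-0.078) or 3 (-0.037) and in 5 fits without 1 array (range -0.035 to 0.11). With the replicate block, 1002 genes were higher and 1344 lower, 147 and 431 by at least 2-fold. Called lower were 12 NK identity, 9 Ly49, 8 cytotoxic, 5 late maturation and 1 acetylcholine receptor genes. So were 12 neutrophil, 8 basophil and mast cell, 8 platelet, 7 erythroid and 4 T cell markers. Called higher were 10 interferon response and 4 MHC class II genes, 9 B cell markers and 1 T cell marker. The cytotoxic and late maturation lists each had 1 gene higher. Of NKT and ILC2/ILC3 markers 6 were higher and 1 lower. The deviations of same-numbered arrays correlated at 0.54, 0.66, 0.52 and 0.03. Arrays numbered 1, 2 and 3 correlated best with the same number in the other group, and those numbered 4 with a number 3. Since those numbered 4 did not pair and the labels state no pairing, the numbers were not taken as pairs. A pairing of the other numbers stays possible, and the fit without a block would leave it out. Blocks for slide and scan could not be fitted, since each group has its own. Between 50.2% and 63.2% of spots were well above background, and signal over background limits dim genes: of 810 called genes, 35 were called by a probe well above background on no array of a group, which allows only a bound, and 89 by a probe above it on some but not all arrays of a group.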

Other observations

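The tests in this part used lists chosen after the values were seen, so they describe the pattern and do not test it independently. Of 16 tested type 17 lymphoid transcripts, 8 were higher in ChAT_positive pools and 0 lower, with a median log2 fold change of 0.87 (camera p = 0.00232 with an estimated correlation). Beyond those already described, they included Maf (0.59, SE 0.15), 5830411N06Rik (1.85, SE 0.20) and Blk (1.01, SE 0.21), which also stands in the B cell list. Of 19 tested type 2 innate lymphoid transcripts, 7 were higher and 0 lower, with a median of 0.61 (camera p = 0.0346 with an estimated correlation). These included Nmur1, the neuromedin U receptor, at 1.96 (SE 0.30, limma adjusted p = 0.0116) and Calca, which encodes calcitonin gene-related peptide, at 1.52 (SE 0.26, adjusted p = 0.017). Il5 and Il9, at 2.29 and 1.85, were not called (adjusted p = 0.0866 and 0.081), nor were Gata3 (-0.21) and Il1rl1 (0.33). Il7r and Rora stand in both lists. Of 10 tested kallikrein 1 family genes, 9 were lower, with a median of -3.49, or -2.14 with genes at their bounds (camera p = 0.0147 with an estimated correlation).

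Adenovirus E1A spike-in probes, which report labelling and hybridisation and not the cells, also differed in level between arrays. Their values are log2 of the processed intensity with no scaling between arrays, unlike the gene values above. Of 10 such probes, 8 had a higher mean log2 signal on the ChAT_positive arrays and 2 a lower one, with differences from -0.048 to 1.46, and in a two-sided exact permutation test without pairs the lowest p was 0.0857 (adjusted over the 10 probes 0.229). With arrays of 1 number set side by side, a comparison chosen after seeing the data although the numbers were not taken as pairs, 7 probes were higher on the ChAT_positive array of all 4 numbers. For these 7 the two-sided exact permutation test within numbers gave p = 0.125, the smallest that 4 numbers allow, so a difference between the slides in these probes was not excluded. The a135 probe had the largest difference between the group means, with 11.9 on ChAT_positive replicate 3 and 10.5 on ChAT_negative replicate 3.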
